A study of Homo sapiens with 4 samples.

How the data were processed

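RNA from the human chondrosarcoma cell line JJ012 was sequenced in 4 libraries, 2 from untreated cells and 2 from cells given 10 µM Antcin K for 24 h. Per the labels' protocols, RNA was harvested with TRIzol and the libraries were run as paired-end reads on an Illumina NovaSeq instrument. The labels give the molecule as total RNA, while the design text of the series speaks of mRNA sequencing. Groups were taken from the treatment in the labels, and the replicate numbers from the sample titles. The labels do not say whether the 2 samples of a group came from separate cultures, and they name no vehicle for the untreated cells.

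Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1 with the genome build hg38. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies, therefore cannot be assigned with certainty. The deposited table holds raw counts per Ensembl gene for each library, with no pooling, for 61806 genes. It also holds FPKM values that the authors scaled by exonic gene length and library total. Recomputing FPKM from the deposited counts, lengths and totals gave every deposited value within 0.00501. Of the gene IDs, 94.3% were in GENCODE release 29, and 71.5% of those had the same start and end there, so coordinates are given as deposited on hg38. The table gives no symbol for 20417 genes, which are named by ID.

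The library totals in the deposited counts were 26270686 and 18757254 for untreated replicates 1 and 2, and 20690078 and 16911257 for Antcin K replicates 1 and 2. Of the 28764 genes with at least 1 count in any library, 14717 passed the edgeR filter filterByExpr at its defaults (a minimum count of 10) and were tested. The counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood method, with group as the only term. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are Antcin K over untreated. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD with n = 2 per group. The median standard error of a log2 fold change was 0.33, and the median biological coefficient of variation was 24.5%. The replicates of each group differed by more than counting noise, with a chi-square per gene of 166 for the untreated pair and 34.8 for the Antcin K pair, so neither pair was treated as a duplicate deposit of one library. This does not show that the samples came from separate cultures.

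Before the data were examined, 48 gene lists were fixed from textbook knowledge and the series title, and 47 had at least 3 tested genes. The list of red blood cell markers had fewer and was not tested. The lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 47 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its p-values from the few residual degrees of freedom of these libraries, so few lists could pass. A loss in that setting therefore does not tell whether correlation between genes removed a call. Over the lists, 61 symbols had no match in the deposited table. GO terms were to be tested for enrichment among called genes, but no gene was called. Camera over the deposited GO biological process terms of 10 to 500 tested genes was added in its place after the data were seen.

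The genes named were set by a rule fixed beforehand. It took MMP7 and up to 6 genes each of the PI3K, Akt and mTOR list and of the NF-kB components by lowest adjusted p. It took the 5 genes with the lowest p in each direction, and up to 4 genes by lowest adjusted p from each list past its test or tied to the series title. Of the genes the rule takes, 2 are not reported here. Genes outside the rule are said to be so where they appear.

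Alternatives fixed beforehand were other scalings, other count filters, DESeq2 1.42.0, limma voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 and without that minimum, a test against a fold of 1.5, the replicate number as a block, and leaving out each library. Alternatives added later were the replicate numbers crossed as a block, removal of a smooth curve of expression on transcript GC content (a spline with 6 degrees of freedom) from each library, and leaving out the mitochondrially encoded genes. GC content came from GENCODE 29 transcripts and was known for 98.9% of the tested genes.

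The tests were tried on simulated data for this comparison, with 200 of 14717 genes changed at the spread estimated from the libraries. The edgeR test recovered 23.9% of the genes changed by 2-fold, 77.6% of those changed by 4-fold and 89.4% of those changed by 8-fold, with 3 false calls. The simulated counts were drawn independently at the dispersion trend, with the same spread in both groups and no shift of a whole library. The real libraries differed in these respects, so the shares may overstate the power of the real test. With 2 samples against 2, an exact permutation test of one value cannot go below p = 0.333, so the p-values given rest on models fitted across all genes.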

Results

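The transcriptome of JJ012 cells, an established line from human chondrosarcoma, a malignant tumour that forms cartilage, was measured with and without Antcin K, a triterpenoid from the medicinal fungus Antrodia cinnamomea. Each group had 2 libraries, with 18757254 and 26270686 counted fragments in the untreated group and 16911257 and 20690078 in the Antcin K group. Nothing says that the samples of a group were separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera with the preset correlation compares a list's genes with the other tested genes. Its p-values measure a spread over genes, not between samples, although genes are not independent replicates. Mitochondrially encoded genes took 26.0% and 12.9% of the counts in untreated replicates 1 and 2, and 13.5% and 19.3% in Antcin K replicates 1 and 2. Across genes, log2 CPM correlated less between the untreated replicates (Pearson r = 0.963) than between the Antcin K replicates (r = 0.984), and untreated replicate 2 correlated more with Antcin K replicate 1 (r = 0.975) than with its own replicate. Genes are not independent replicates, so these values describe the libraries only.

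The comparison of Antcin K with untreated cells asks which transcripts differ after 24 h at 10 µM, and the series title ties it to MMP-7, to PI3K, Akt and mTOR, to NF-κB and to cell motility. Collagen and fibrillar matrix genes had lower means as a group after Antcin K, as did fibroblast markers, angiogenic factors, mesenchymal and migration genes, and integrin and focal adhesion genes. Autophagy and lysosome genes and the targets of NRF2, the transcription factor of the antioxidant response, had higher means as groups. These 7 of 47 lists passed camera with its preset correlation between genes, while with an estimated correlation each had an adjusted p = 0.869. The estimates were 0.43 for collagens, 0.21 for integrins, 0.20 for mesenchymal genes and 0.18 for angiogenic factors. For fibroblast markers, autophagy genes and NRF2 targets they were -0.02, 0.02 and 0.04, near the preset 0.01. All these estimates rest on the few residual degrees of freedom of 4 libraries, so they cannot show that the preset suits a list. Across the 14717 genes past the count filter, called all genes below, edgeR called 0 and DESeq2 53, while edgeR called 208 without that filter and 26 with the replicate number as a block. DESeq2 gave no adjusted p to 1427 of the filtered genes, NFKBIZ and COL3A1 among them, so its calls are over the rest. MMP7, the matrilysin gene, stood at 3.23 ± 0.22 CPM in untreated cells and 4.49 ± 0.60 CPM after Antcin K (SD, n = 2 per group), a difference that did not pass.

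MMP7 (ENSG00000137673, chromosome 11, 102520508 to 102530750, minus strand, hg38, protein-coding) had 90 and 55 counts in the untreated libraries and 106 and 68 in the Antcin K libraries. Its log2 fold change was 0.47 with a standard error of 0.33 and a 95% interval of -0.29 to 1.23 (edgeR, adjusted p = 0.568), and was 0.31 without Antcin K replicate 1. Both Antcin K libraries, at 4.91 and 4.06 CPM, lay above both untreated libraries, at 3.39 and 3.08 CPM. Of the 15 tested matrix metalloproteinases and their inhibitors, 6 had a higher and 9 a lower mean after Antcin K, and by edgeR 0 passed either over all genes or adjusted over the list alone. Without the count filter MMP2 passed (adjusted p = 0.0482), while without untreated replicate 1 its log2 fold change was -0.47. MMP3, stromelysin 1, stood at 25.6 ± 5.88 CPM untreated and 43.6 ± 3.41 CPM after Antcin K (log2 fold change 0.77), and MMP2, gelatinase A, at 28.9 ± 15.2 and 13.1 ± 3.49 CPM (-1.14). The membrane-type enzyme MMP17 had a log2 fold change of -0.84, or -0.34 without untreated replicate 1, and the inhibitor TIMP3 one of -0.42, or -0.27 without that library. As a list they did not pass (camera, adjusted p = 0.870), and the direction of that test turned without untreated replicate 1 and without Antcin K replicate 1 (adjusted p = 0.830 and 0.998).

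Of 31 tested components of the PI3K, Akt and mTOR pathway, 13 had a higher and 18 a lower mean after Antcin K, and by edgeR 0 passed over all genes or adjusted over the list alone. PIK3CA, which encodes the catalytic subunit p110α of PI3K, had 154 and 514 counts in the untreated libraries and 79 and 41 after Antcin K, a log2 fold change of -2.48 with a standard error of 0.67. The untreated libraries differed from each other there, at 5.80 and 28.8 CPM. Over all genes PIK3CA was called by DESeq2 (adjusted p = 0.0106) and by edgeR with the replicate number as a block (0.0203). It also passed in edgeR without the count filter (1.30e-06), on a larger set of genes and despite that gap between the untreated libraries. Its log2 fold change without untreated replicate 2 was -0.91. DEPTOR, an inhibitor of mTOR kinase, stood at 0.909 ± 0.098 CPM untreated and 3.13 ± 1.41 CPM after Antcin K (log2 fold change 1.76, standard error 0.47), and passed without the count filter (adjusted p = 0.0400). The translation repressor gene EIF4EBP1 had a log2 fold change of -0.63, the tuberous sclerosis gene TSC1 one of 0.60, the lipid phosphatase gene INPP4B one of -0.81 and the mTOR complex subunit gene MLST8 one of -0.60. Without untreated replicate 1 the value of INPP4B was -0.50, and without untreated replicate 2 that of MLST8 was -0.35. On the filtered genes, adjusted p for these 6 lay between 0.366 and 0.406 (edgeR). The list did not pass (camera, adjusted p = 0.915), and the test's upward direction was opposite in sign to the list's mean of -0.07 and median of -0.04, and without untreated replicate 1 the mean was 0.06.

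Among 22 tested NF-κB components and targets, 9 had a higher and 13 a lower mean after Antcin K, and by edgeR 0 passed over all genes or adjusted over the list alone. NFKBIZ, an atypical nuclear IκB protein gene, had 49 and 17 counts untreated and 4 and 4 after Antcin K, a log2 fold change of -2.72 with a standard error of 0.65, and passed without the count filter (adjusted p = 0.0331). It overlaps NXPE3 on the same strand, which holds 3100 counts over the 4 libraries against 74 for NFKBIZ. The kinase gene IKBKB had a log2 fold change of 0.56 and its partner CHUK one of -0.70, the subunit genes RELA and RELB had -0.52 and -0.45, and the target genes TRAF1 and IER3 had -0.90 and -0.64. The groups overlapped for CHUK and RELA, whose log2 fold changes were -0.09 without untreated replicate 2 and -0.07 without untreated replicate 1, and RELB had -0.14 without Antcin K replicate 2. NFKBIB, which overlaps SIRT2 on the opposite strand, had -0.19, a sign that turned without untreated replicate 2 and after removal of the GC trend (0.10 in both). Its groups overlapped as well, at 15.0 and 21.6 CPM untreated and 17.1 and 14.9 CPM after Antcin K. The adjusted p of these 8 genes ran from 0.366 to 0.799 (edgeR), and the list had an adjusted p = 0.396 (camera, mean log2 fold change -0.33).

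Of 26 tested collagen and fibrillar matrix genes, 24 had a lower mean after Antcin K and 2 a higher one, with a mean log2 fold change of -0.86 (camera, adjusted p = 3.30e-05, and adjusted p = 0.869 with an estimated correlation). COL1A2, a chain of type I collagen, stood at 11.3 ± 7.02 CPM untreated and 3.69 ± 0.44 CPM after Antcin K (log2 fold change -1.62). COL3A1, the chain of type III collagen, had 46 and 15 counts untreated and 3 and 6 after Antcin K (-2.42). COL8A1 had a log2 fold change of -2.08, and FBLN1, the gene of the matrix glycoprotein fibulin 1, one of -1.04. By edgeR 0 of the 26 passed over all genes, and 5 passed adjusted over the list alone, these 4 and THBS1. DESeq2, which gave COL3A1 no adjusted p, called 1 of them over all genes, COL8A1 (adjusted p = 0.0220). Without the count filter edgeR called 4, COL1A1, COL1A2, COL8A1 and THBS1. Without untreated replicate 1 the log2 fold change of COL1A2 was -0.78 and that of COL8A1 -1.31. Of the 8 tested fibroblast markers, 4 of which are also in the collagen list, 6 had a lower mean (mean log2 fold change -1.01, camera, adjusted p = 0.00616, and adjusted p = 0.869 with an estimated correlation). The 4 shared genes all had lower means, so the 2 markers with a higher mean were outside the collagen list. FAP, the gene of fibroblast activation protein, stood at 10.3 ± 3.39 CPM untreated and 2.71 ± 0.364 CPM after Antcin K (log2 fold change -1.92). Adjusted over the list alone, 5 of the 8 passed, namely FAP, FBLN1, COL1A2, COL3A1 and COL1A1, the last named after its values were seen, and by edgeR 0 passed over all genes. All of these but FAP are also in the collagen list. FAP was called over all genes by DESeq2 (adjusted p = 0.00762) and with the replicate number as a block (0.0353), and FAP, COL1A1 and COL1A2 without the count filter. Untreated replicate 1, the library with the highest mitochondrial share, also had the highest mean of both lists. Without it the collagen call was lost (mean log2 fold change -0.39), and the fibroblast call held (-0.78). The lists share 4 genes, so these are not independent results.

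Of 25 tested mesenchymal and migration genes, 21 had a lower mean after Antcin K (mean log2 fold change -0.47, camera, adjusted p = 0.0323, and adjusted p = 0.869 with an estimated correlation). CDH11, a mesenchymal cadherin gene, stood at 22.9 ± 6.09 CPM untreated and 7.85 ± 0.815 CPM after Antcin K (log2 fold change -1.55). The transcription factor gene TWIST1 had -1.21, and SNAI2 stood at 4.76 ± 1.35 CPM untreated and 2.39 ± 0.421 CPM after Antcin K. Among 25 tested integrin and focal adhesion genes, 20 had a lower mean (mean log2 fold change -0.37, camera, adjusted p = 0.0323, and adjusted p = 0.869 with an estimated correlation). ITGB1, the β1 integrin gene, stood at 127 ± 38.5 CPM untreated and 48.8 ± 2.22 CPM after Antcin K (log2 fold change -1.38), ITGAV had -1.58 and CAV1 -0.90. ZYX, the zyxin gene, had 142 and 41.7 CPM untreated and 22.6 and 46.2 CPM after Antcin K, so its groups overlapped, and its log2 fold change of -1.42 was -0.28 without untreated replicate 1. Without that library ITGAV had -0.87 and SNAI2 -0.66. Among 16 tested angiogenic factors, 12 had a lower mean (mean log2 fold change -0.52, camera, adjusted p = 0.0323, and adjusted p = 0.869 with an estimated correlation). NRP1, the neuropilin 1 gene, stood at 47.8 ± 17.6 CPM untreated and had a log2 fold change of -1.25, or 2.39-fold lower after Antcin K. PDGFB had -0.90 and PDGFC -1.09. THBS1, the gene of the angiogenesis inhibitor thrombospondin 1 and also in the collagen list, had -1.62, so the list mixes genes of opposite effect. NRP1 had -0.82 without untreated replicate 2, and PDGFC -0.71 without untreated replicate 1. Adjusted over the list alone, CDH11 passed in the first list, ITGB1 and ITGAV in the second and NRP1 in the third, and by edgeR 0 genes of any of them passed over all genes. DESeq2 called CDH11 (adjusted p = 0.0106), ITGB1 (0.0130) and ITGAV (0.0386) over all genes. Without the count filter edgeR called these 3, NRP1, THBS1 and ZYX among the genes named here. Without untreated replicate 1 the 3 calls were lost (adjusted p = 0.805, 0.335 and 0.141), and the mean log2 fold changes were -0.19 for mesenchymal genes, -0.15 for integrins and -0.32 for angiogenic factors. The calls were also lost without Antcin K replicate 1 (0.0696, 0.145 and 0.188). The integrin call was lost on ranks as well (0.0591), and the angiogenic call after removal of the GC trend (0.0555).

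Of 40 tested autophagy and lysosome genes, 30 had a higher mean after Antcin K, with a mean log2 fold change of 0.22 (camera, adjusted p = 0.00616, and adjusted p = 0.869 with an estimated correlation). CTSL, the gene of the lysosomal protease cathepsin L, stood at 59.9 ± 17.7 CPM untreated and 106 ± 5.62 CPM after Antcin K (log2 fold change 0.82, or 0.55 without untreated replicate 1). The cholesterol transporter gene NPC2 had 0.66, the sialidase gene NEU1 0.71 and the autophagosome gene GABARAPL1 0.76. This call held without each of the 4 libraries in turn, with adjusted p from 7.89e-05 to 0.0489. Of 24 tested NRF2 target genes, 16 had a higher mean (mean log2 fold change 0.25, camera, adjusted p = 0.0323, and adjusted p = 0.869 with an estimated correlation). The mean ran from 0.17 without untreated replicate 1 to 0.41 without untreated replicate 2. SRXN1, the sulfiredoxin gene, stood at 1.96 ± 0.797 CPM untreated and 5.38 ± 1.77 CPM after Antcin K (log2 fold change 1.47). The thioredoxin reductase gene TXNRD1 had 0.69, the glutathione reductase gene GSR 0.65 and the cystine transporter gene SLC7A11 0.63, or 0.38 without Antcin K replicate 1. In both lists 0 genes passed by edgeR over all genes or adjusted over the list alone, and SRXN1 passed without the count filter (adjusted p = 0.0438). The NRF2 call was lost without untreated replicate 1 (mean log2 fold change 0.17, adjusted p = 0.306), Antcin K replicate 1 (0.0696) or Antcin K replicate 2 (0.0632). NPC2 overlaps ISCA2 on the opposite strand and TXNRD1 overlaps the pseudogene RPL18AP3, so their counts are less certain.

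**Figure D1:**
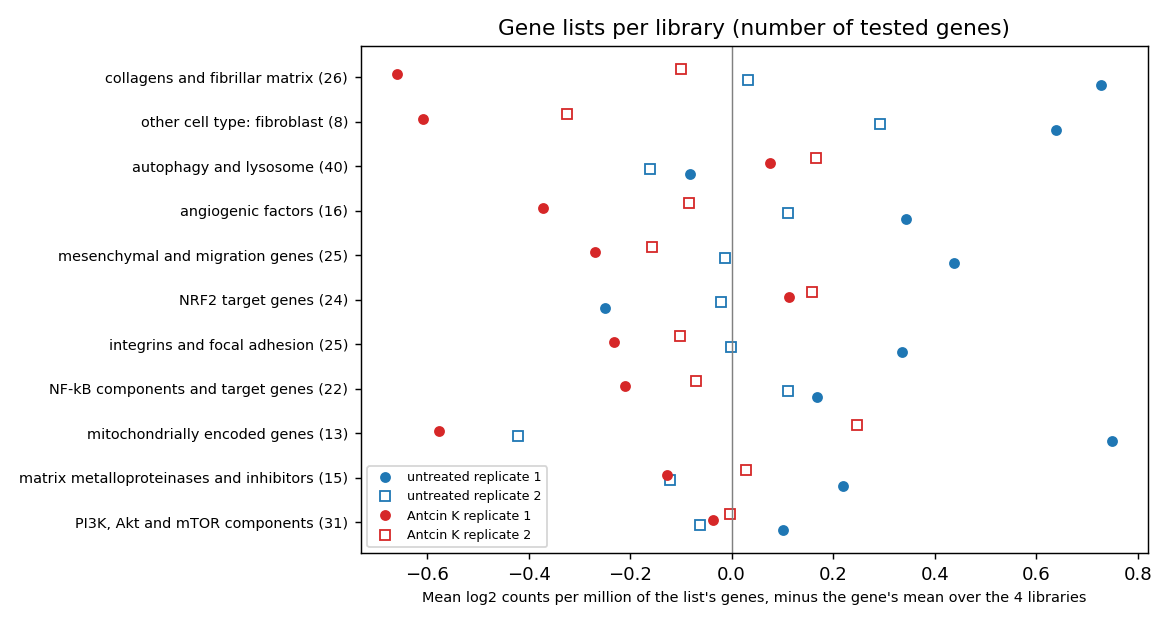
Mean log2 CPM of each list's tested genes (number in brackets), centred on each gene's mean over the 4 libraries (x axis, log2 units), with 1 point per library. In the collagen list untreated replicate 1 lies at 0.73 and Antcin K replicate 1 at -0.66, with the other 2 libraries at 0.03 and -0.10.

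Among single genes, the lowest p for a lower mean belonged to CCN4, a matricellular protein gene and Wnt target, at 3.95 ± 0.115 CPM untreated and 0.365 ± 0.00851 CPM after Antcin K, or 10.7-fold lower (107 and 69 counts against 8 and 6). DEPP1, a FOXO-regulated gene, was next at 27.2 ± 1.97 and 7.43 ± 0.367 CPM. The cytoskeletal gene SEPTIN7 had a log2 fold change of -1.52 and the gap junction gene GJA1 (connexin 43) one of -1.56. On the higher side, CRBN, the gene of the ubiquitin ligase receptor cereblon, stood at 7.90 ± 2.29 CPM untreated and 25.5 ± 3.85 CPM after Antcin K, or 3.24-fold higher. ENSG00000249849 (chromosome 5, 177682294 to 177713969, plus strand) had 6 and 6 counts untreated and 70 and 35 after Antcin K, and it overlaps FAM153A on the opposite strand. MRNIP had a log2 fold change of 1.41, the choline kinase gene CHKA one of 1.09 and the TGF-β signalling repressor gene TGIF1 one of 1.11. Each of these 9 genes had an adjusted p = 0.366 by edgeR, so they are named by rank. DESeq2 called 8 of them, all but CHKA, with adjusted p from 0.000115 for DEPP1 to 0.0475 for TGIF1. With the replicate number as a block, edgeR called CCN4, DEPP1, CRBN and ENSG00000249849, and without the count filter it called all 9. MRNIP, with 1039 counts over the 4 libraries, overlaps SQSTM1 on the opposite strand (270994 counts) and TBC1D9B on its own strand (12775 counts), and CRBN and DEPP1 overlap TRNT1 and RASSF4 on the opposite strand.

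**Figure D2:**
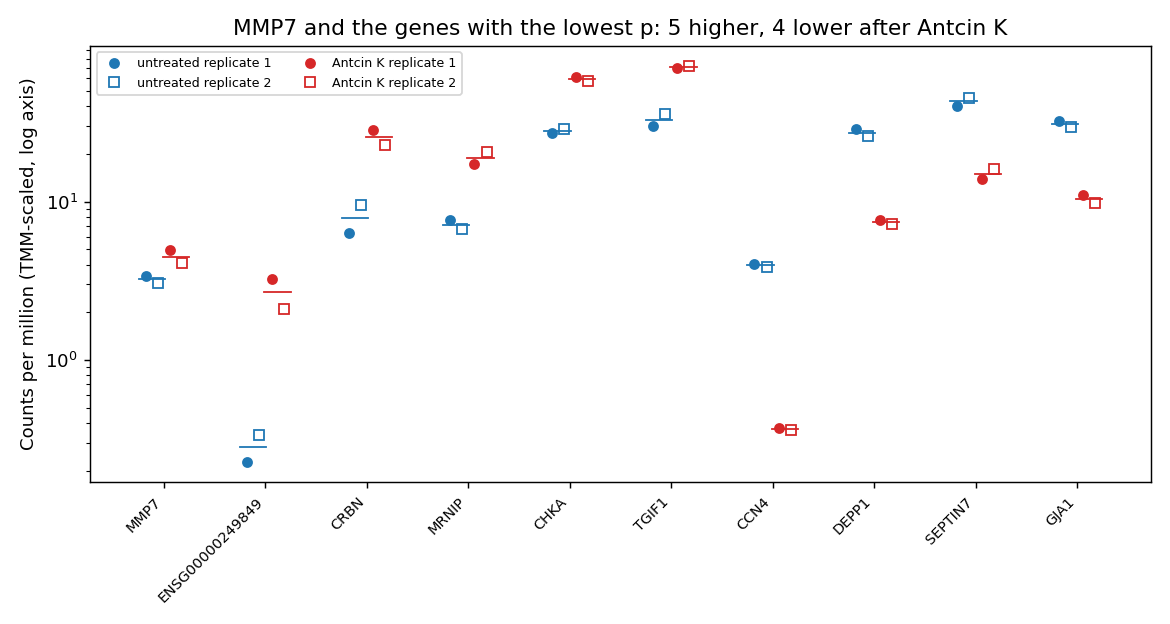
CPM on a log axis for MMP7, the 5 genes with the lowest p for a higher mean and the 4 with the lowest p for a lower mean after Antcin K, with 1 point per library and a bar at each group mean (n = 2). CCN4 lies near 4 CPM in both untreated libraries and near 0.4 CPM in both Antcin K libraries, and MMP7 lies between 3.08 and 4.91 CPM in all 4.

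Across the 14717 genes tested, edgeR called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.366. At an unadjusted p under 0.05 there were 1821 genes, 701 higher and 1120 lower after Antcin K, against the 736 that 5% of the genes would give. DESeq2 called 53 genes, 5 higher and 48 lower, with 1522 at an unadjusted p under 0.05, and limma voom called 0, with 1807. On the same 4 libraries edgeR called 208 genes without the count filter and 26 with the replicate number as a block. The unfiltered fit also called ZYX (edgeR, adjusted p = 0.00363), whose groups overlapped, while the stricter filter gave 0 calls. Passing without the filter therefore does not mean that the groups were apart. The groups did not overlap for 45.8% of the genes, where chance gives 33.3%, with 3319 genes higher and 3423 lower in both Antcin K libraries. Leaving out 1 library changed the edgeR count to 1432 without untreated replicate 1, 3971 without untreated replicate 2, 7 without Antcin K replicate 1 and 3 without Antcin K replicate 2. In these fits the lone library of a group is assumed to vary like the other group.

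The median log2 fold change also ran with transcript GC content. With the tested genes in 10 bins of equal size, it was -0.34 in the bin with the lowest GC content, 0.19 in bins 5 and 6 and -0.40 in the highest. After the GC trend was removed from each library, the medians lay between -0.09 and -0.01, and edgeR called 0 genes, with 1440 at an unadjusted p under 0.05. In the untreated libraries, deviations from each gene's mean also ran with exonic gene length. Spearman's coefficient was 0.16 and -0.20 in untreated replicates 1 and 2, and -0.03 and 0.002 in Antcin K replicates 1 and 2. No fit removed the trend with length.

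**Figure D3:**
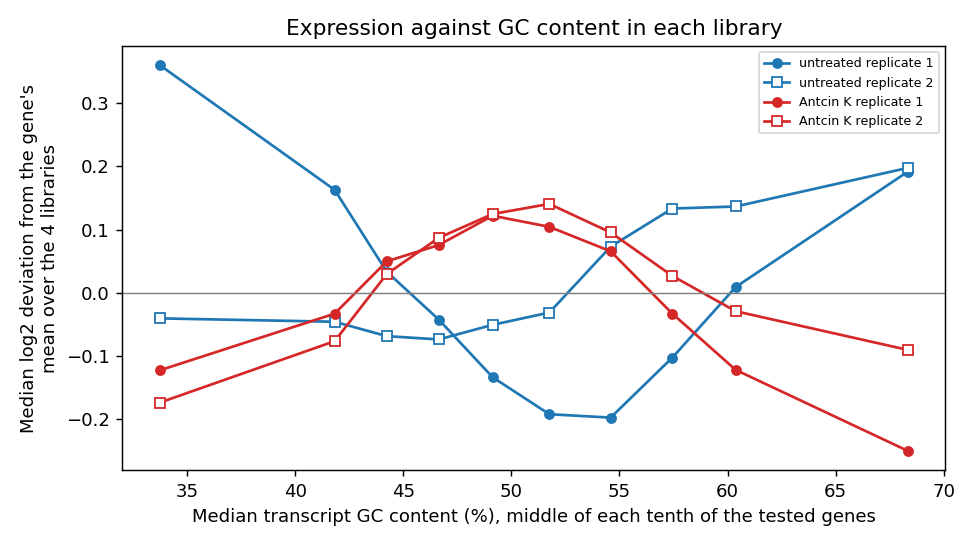
Median log2 deviation of a library from each gene's mean over the 4 libraries (y axis), for 10 bins of tested genes by median transcript GC content in percent (x axis), with 1 line per library. Both Antcin K libraries peak at middle GC content, while untreated replicate 1 is lowest there, at -0.20, and highest, at 0.36, in the bin with the lowest GC content.

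The other 37 lists did not pass camera on the 4 libraries with the preset correlation, and 9 of them passed in another setting. Apoptosis regulators came closest, with 20 of 26 genes higher (adjusted p = 0.0551), and passed on ranks (0.0483), without untreated replicate 2 (0.0408) and without Antcin K replicate 2 (0.0364). Next were metallothioneins and zinc transport and nuclear-encoded oxidative phosphorylation (0.202 each). Cartilage matrix and chondrocyte genes, with 11 of 16 lower, osteoblast markers and the unfolded protein response each had an adjusted p = 0.225. Interferon-stimulated genes had 0.274, mitosis genes 0.280, and the proteasome and Wnt target lists 0.311 each. The p53 targets, cytosolic ribosomal proteins, S phase genes and FOXO targets each had 0.396, and the mitochondrially encoded genes, 12 of 13 lower, and TGF-β targets each had 0.435. The ADAM and ADAMTS proteases had 0.463, cytosolic heat shock genes 0.496, and epithelial markers and ribosome biogenesis genes 0.521 each. Fatty acid synthesis and YAP and TAZ targets had 0.565 each, replication-dependent histones 0.668, transfer RNA synthetases 0.728, and endothelial markers and immediate early genes 0.783 each. Glycolysis, MHC class I antigen presentation and hypoxia targets had 0.870 each, and cholesterol synthesis and cell cycle entry genes 0.882 each. The aryl hydrocarbon response, liver X receptor targets, leukocyte markers, the ATF4 response, glucocorticoid receptor targets and nuclear noncoding RNA each had 0.915. Without untreated replicate 2, the mitochondrially encoded genes (9.81e-06) and metallothioneins (0.0348) passed as lower, and oxidative phosphorylation (6.09e-05), ribosomal proteins (0.000138) and the proteasome (0.00803) as higher. Without untreated replicate 1 the direction turned for 4 of these, to higher for the mitochondrially encoded genes (0.0826) and to lower for oxidative phosphorylation (0.498), ribosomal proteins (0.141) and the proteasome (0.979), and it also turned for the mitochondrially encoded genes without Antcin K replicate 1 (0.845). Without Antcin K replicate 2, metallothioneins (0.0178), cartilage matrix genes (0.0202) and osteoblast markers (0.0419) passed as lower and oxidative phosphorylation (0.0393) as higher, and without untreated replicate 1 the unfolded protein response passed as higher (0.0232). Adjusted over the list alone, 5 of these lists had 1 gene past 0.05, namely CCN4 (Wnt targets), TXNIP (FOXO targets), PHLDA1 (immediate early genes), SLC39A10 (zinc transport) and KRT18 (epithelial markers), of which all but CCN4 lie outside the naming rule and were named after their values were seen.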

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

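The GC removal, the crossed numbers and the omission of mitochondrial genes were chosen after seeing the data. Without a count filter edgeR called 208 genes (44 higher, 164 lower), and DESeq2 called 53 (5 higher, 48 lower). The 5 higher were ENSG00000249849, CRBN, MRNIP, TGIF1 and GCNT3, the last chosen after its values were seen. Leaving out 1 library gave 3 to 3971 calls (0 to 1964 higher, 1 to 2007 lower) and 448 to 5434 genes at an unadjusted p under 0.05. The 3 calls without Antcin K replicate 2 were ENSG00000280614 and ENSG00000249849, higher, and IL7R, lower, the first and last chosen after their values were seen. The test against a fold of 1.5 gave 0 calls and 638 such genes. The other scalings, the stricter filter, voom, the 3 FPKM fits, GC removal and the omission of mitochondrial genes also gave 0 calls, with 1440 to 2154 such genes. In a fit without an untreated library, the spread of a gene came from the Antcin K pair alone (chi-square per gene 34.8). Without an Antcin K library it came from the untreated pair alone, which differed more (166). The counts of these fits are therefore not comparable with those on all libraries. The chi-square used library totals without TMM and grows with a gene's count. It describes the pairs and is not the spread that these fits used. The cause of the other changes was not tested. MMP7 was higher under all 18 alternatives run (log2 fold change 0.31 to 0.63) and passed in none of them, with adjusted p from 0.415 to 1.00.

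The replicate numbers are shared by the groups, but no label says that they pair the samples, and the differences between numbers 1 and 2 correlated at -0.32 across genes between the groups. With the replicate number as a block, edgeR called 26 genes (4 higher, 22 lower), with 1157 at an unadjusted p under 0.05, and 20 of the 26 were also called by DESeq2. The 4 higher were ENSG00000280614, ENSG00000249849, CRBN and GCNT3. The block left 7 lists past the threshold and changed no list call. With the numbers crossed as a block there were 1430 calls (583 higher, 847 lower) and 3427 genes at an unadjusted p under 0.05. This block was chosen after the data were seen. The split it takes out gave 904 genes at an unadjusted p under 0.05 by edgeR. The split it leaves as the spread, replicate 1 against replicate 2, gave 108, so more calls were built into the choice.

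Of the 7 lists past camera, 0 passed with an estimated correlation (adjusted p = 0.869 each) or by fry (0.697 each). Leaving out 1 library left 3 to 13 lists past, with adjusted p from 3.71e-12 to 0.141 for collagens, 0.00657 to 0.188 for angiogenic factors, 0.00214 to 0.805 for mesenchymal genes, 0.00663 to 0.306 for NRF2 targets and 0.000990 to 0.335 for integrins. Angiogenic factors were lost after GC removal (0.0555), which left 6 lists, and integrins on ranks (0.0591). Among the lists tied to the series title, the direction turned for the metalloproteinase list (adjusted p 0.242 to 0.998 without 1 library) and for the PI3K list (0.659 to 0.998, and 0.992 by fry). The causes were not tested. NFKBIB turned to 0.10 after GC removal and ran from -0.43 to 0.10 without 1 library. Among the other values of named genes, 813 kept direction and side of the threshold and 123 passed it, of which 44 were without untreated replicate 2, 31 without untreated replicate 1, 25 without a count filter, 15 by DESeq2 and 6 with the block. GO enrichment among called genes was not run, having no called gene as input. MMP7, with 55 to 106 counts per library, had a 95% interval of -0.29 to 1.23 and a standard error of 0.33, as was the median over tested genes, and whether depth or the spread between libraries set it was not tested.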

Other observations

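The GO terms, the leave-one-library-out tests of explanations and the splits were chosen after the results were seen, and the GC tests were set before theirs. The genes named in this paragraph were chosen after their values were seen. IL7R, the gene of the interleukin 7 receptor α chain, stood at 16.4 and 56.2 CPM in the untreated libraries and at 4.49 and 3.29 CPM after Antcin K. It had the lowest adjusted p in DESeq2 (7.53e-07), and edgeR also called it with the replicate number as a block, without Antcin K replicate 1 and without Antcin K replicate 2. It was not called by edgeR on all 4 libraries with group as the only term (adjusted p = 0.366). ANXA1, the annexin A1 gene, had 106 and 66.4 CPM untreated and 29.8 and 34.2 CPM after Antcin K, and was called by DESeq2 (adjusted p = 0.0120). TXNIP, the gene of the thioredoxin-interacting protein, stood at 15.9 ± 1.53 CPM untreated and 34.8 ± 4.10 CPM (SD, n = 2 per group) after Antcin K, and was called by edgeR without the count filter (adjusted p = 0.0235) but not on the filtered genes (0.366).

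Of 1871 GO biological process terms, camera called 0, with 134 at an unadjusted p under 0.05 and a smallest adjusted p of 0.235. After GC removal 0 terms were called, 1 without untreated replicate 1 (ribosomal small subunit assembly, lower, adjusted p = 0.00757) and 6 without untreated replicate 2, among them translation (higher, 0.00119), mitochondrial translation (higher, 0.0316) and aortic valve morphogenesis (lower, 0.0244). Without untreated replicate 1 the direction was lower for translation (0.843) and mitochondrial translation (0.931). In extracellular matrix organization, 57 of 80 genes had a lower mean after Antcin K, with a mean log2 fold change of -0.32 (adjusted p = 0.646). In collagen fibril organization 24 of 40 genes had a lower and 16 a higher mean (camera, adjusted p = 0.646). In cell migration 114 of 196 genes had a lower mean (adjusted p = 0.853). Autophagy, with 65 of 122 genes higher (adjusted p = 0.837), and lysosome organization, with 22 of 38 higher (adjusted p = 0.950), did not pass either.

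Collagen and fibroblast marker genes had lower means after Antcin K. The tables argue against the GC trend of the libraries as the whole cause. After its removal the mean log2 fold change was -0.86 for collagens (camera, adjusted p = 7.74e-05) and -1.02 for fibroblast markers (camera, adjusted p = 0.00310). Before removal both list calls were lost with an estimated correlation (camera, adjusted p = 0.869 each). With that setting 0 lists passed, so the losses do not tell whether correlation between genes removed the calls. Both untreated libraries had a higher mean of the fibroblast markers (0.64 and 0.29, centred log2 CPM) than both Antcin K libraries (-0.61 and -0.32). Without untreated replicate 1 the mean log2 fold change was -0.78, with a standard error over genes of 0.23. Only untreated replicate 2 was then left as control, and genes are not independent replicates. This value therefore cannot decide how much untreated replicate 1 contributed. For collagens that library and the treatment cannot be told apart, since without it the mean was -0.39 with a standard error over genes of 0.15, which lies below 0, while the list test no longer passed (adjusted p = 0.141). An effect of Antcin K may be involved as a hypothesis, and differences between cultures or in the mix of cells, for which the labels give no handle, were not tested. The trend of the untreated libraries with gene length was not tested as a cause either.

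Autophagy and lysosome genes had higher means after Antcin K. The tables argue against the GC trend as the whole cause, since the mean log2 fold change after its removal was 0.20 (camera, adjusted p = 0.00310). Both untreated libraries had a lower mean of the list (-0.08 and -0.16, centred log2 CPM) than both Antcin K libraries (0.08 and 0.17). Without untreated replicate 1 the mean log2 fold change was 0.29, with a standard error over genes of 0.05. Only untreated replicate 2 was then left as control, so this value cannot decide how much untreated replicate 1 contributed. The list call was lost with an estimated correlation (camera, adjusted p = 0.869). With that setting 0 lists passed, so the loss does not tell whether correlation between genes removed the call. The GO term for lysosome organization had a mean log2 fold change of -0.002. A response to Antcin K may be involved as a hypothesis, beside differences between cultures and the trend with gene length, which were not tested.

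More genes had an unadjusted p under 0.05 than 5% of those tested, 1821 against 736. Removal of the GC trend left 1440, which is between the bounds set for the trend as the whole cause and for no part in it, so the trend's share and the treatment's cannot be told apart by this count. Only 3 splits of the 4 libraries into 2 and 2 exist, too few for a share under 0.05, and 1 of them, the real one, gave as many genes, with 904 as the highest of the others. That split set untreated replicate 1 and Antcin K replicate 2 against the other 2 libraries.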
